A study of Dinoroseobacter shibae with 40 samples.

How the data were processed

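Dinoroseobacter shibae DFL12T was grown in the dark in a chemostat at 30 °C and pH 8 in salt-water minimal medium, with 0.7 l/min of air, stirring at 150 rpm and a dilution rate of 0.1 per h. Oxygen saturation was 85% before aeration was stopped, and the culture had run for 20 h. Samples of 2 ml were taken 5, 10, 15, 20, 30, 60 and 120 min after the shift, and 2 µg of RNA was labelled for each hybridisation, per the labels' protocols. Each anaerobic sample shared an array with aerobic RNA. The labels give 3 biological replicates at 6 times and 2 at 60 min (labelled 1 of 2 and 2 of 2). Each has a technical replicate of opposite dyes, so that 40 arrays were used. The labels do not say whether the aerobic RNA was pooled or taken from each culture.

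Spot intensities of the green (Cy3) and red (Cy5) channels were extracted by the authors with Agilent Feature Extraction 10.7.3.1, per the file headers. The deposited scanner files hold raw mean intensities, median local background intensities, and processed intensities that the scanner software had background-subtracted with spatial detrending and dye-normalized, besides flags for outliers, saturation and signal well above background. A deposited series matrix holds log2 values. Limma is named in the submitters' processing notes, with neither version nor methods given in the sources used here. The matrix columns were set against log2 red over green computed from the scanner intensities and normalized as described below. They correlated by 0.861 to 0.996 on every array, so scale (log2) and direction (Cy5 over Cy3, dye swaps not turned) were read from the values. The medians of the columns lay between −0.0491 and 0.0319, and 210 values were missing. The centring method of the authors stays unknown. These values served as an alternative.

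Arrays were read in R 4.3.3 with the data.table package (1.17.8) and processed with limma 3.58.1. Mean intensities were corrected with normexp (offset 50) on all 14999 features, and log2 ratios were normalized by loess within each array, with weight 0 for 687 control features and for spots with outlier marks (0.29% to 1.96% per array). No spot was saturated (0 on all arrays). Ratios were turned to anaerobic over aerobic by the dyes in the labels. The 204 probes printed as 10 spots each were averaged. Of 12476 probes, 9970 were well above background in either channel on at least 4 arrays and were kept. A gene's value was the median over its kept probes: 472 genes had 1 kept probe, 603 had 2, 2631 had 3 and 69 had more, giving 3775 genes. The 2 dye orientations of a biological replicate were averaged to 1 value. Gene names are those of the array design, updated by locus tag from a RefSeq table of assembly ASM1814v1; 3980 of 4102 gene identifiers matched and 122 kept the name on the array. No genome coordinates were used.

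Each time was tested against 0 in 1 limma model (lmFit and eBayes, two-sided) over the 20 values and 7 times, which share an estimate of the spread (15.73 degrees of freedom, of which 2.73 are prior), with Benjamini-Hochberg adjustment over all genes at 0.05. Differences between times were contrasts in the same model, and an F test covered the 6 differences from 5 min. The main tests, most alternatives, 33 gene lists defined by symbol and product text and the rule for named genes were fixed before the data were examined; later additions are named as such in the sections that use them. Lists with at least 3 measured members (32) were tested at each time with limma's camera at a preset correlation of 0.01, with adjustment over the 224 pairs of list and time. The aa3 oxidase and complex I lists, drawn up later, were adjusted over their own 14 pairs, so their adjusted p is not on the scale of the other lists, and all lists between times over 170 pairs. It called 87 pairs; the 2 that held with an estimated correlation were the cbb3 oxidase at 10 and 15 min. Where a list call is printed with the p of the estimated correlation alone, it had passed with the preset one. Genes named in the text were taken, at each time, from up to 12 largest rises and 12 largest falls that passed with all replicates of the same sign; from up to 6 members per list with the smallest p of any change; from up to 6 rises and 6 falls per contrast of 30 with 5, 120 with 30 and 120 with 5 min; and from all Crp/Fnr regulators. This rule took 247 genes.

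A gene whose probes were not well above background on any array in one channel has only a bound there, given as at least N-fold: the mean of the bright channel over the mean of the dim one, each array of the dim channel taken at the higher of the gene's own signal and the lowest signal well above background, after loess and Aquantile. Of the genes called at 30, 60 and 120 min, 16, 15 and 20 were dim in the aerobic channel. The number of arrays limits the precision, and the share of probes well above background per array (12.4% to 82.7%) limits the dim genes.

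The steps were tested on simulated data for the 3775 genes. At 30 min 51.4%, 90.8% and 99.1% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered, and 3.8% of calls were false. At 60 min 42.6%, 77.3% and 96.6% were recovered, with 4.72% of calls false. For 30 against 5 min 30.9%, 72.8% and 96.0% were recovered, and for 120 against 30 min 27.1%, 72.5% and 96.9%. The F test recovered 67.9%, with 3.69% of calls false. A list shifted at one time was found in 5 of 5 simulations, with 0 false calls in 1120 pairs. The simulated values were independent between genes and samples, with the same spread of a gene at all times. In the real data the estimated correlation between genes was 0.861 for ribosomal protein genes and 0.775 for cbb3 genes. The simulations also held no structure of replicates or slides, so their false shares do not give the error rates of the real calls. A 4-fold rise put into the raw 5 min arrays for 200 genes was called in all 200, with a median log2 value of 2.35 found where 2 was put in above local background, and 7 other genes were called. The quartiles found were 2.19 and 2.50, so log2 ratios and folds given below may be too large as well.

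The replicate numbers come from the labels, and whether they pair the samples was checked by correlating, over genes, the deviations of same-numbered samples from their time's mean. The correlations were 0.323, 0.611 and 0.622 for replicates 1, 2 and 3 between 30 and 120 min, and also over 0.1 throughout between 10 and 15, 15 and 20, and 20 and 30 min, so these were taken as paired. The arrays lay on 6 slides. Each replicate number had a slide for 5 to 20 min and a slide for 30 to 120 min, except that 10 and 15 min replicate 3 lay on the late slides of replicates 1 and 2. Alternatives were no background subtraction, the scanner's processed signals, median centring, Aquantile, the series matrix, the mean over probes, no filter and a stricter filter (8106 probes), replicate number and slide as blocks, each dye orientation alone, the spread of the compared times alone, other list tests, and each sample or replicate number left out. Of other splits of the samples, all 10 were counted for 2 times with 3 samples each, and for the F test 100 assignments were drawn over all samples and 100 within replicate numbers.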

Results

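The study followed the transcriptome of Dinoroseobacter shibae DFL12T, a marine alphaproteobacterium that makes bacteriochlorophyll and can denitrify, after aeration of a continuous culture was stopped. RNA taken 5, 10, 15, 20, 30, 60 and 120 min after the shift was hybridised on 2-colour arrays against RNA of the aerobic culture, with 3 biological replicates at 6 times and 2 at 60 min. Each biological replicate was hybridised again with the dyes exchanged, so that the 40 arrays gave 20 biological values per gene. Values are mean log2 ratios of anaerobic over aerobic RNA ± SE of the fit, over 3 replicates, or over 2 at 60 min. Between 12.4% and 82.7% of the probes on an array were well above background, with a median of 61.3%. The number of arrays limits the precision: the median SE of a gene was 0.13, and 0.16 at 60 min. A test against 0 leaves out the spread of the aerobic culture itself. The labels call the replicates biological without saying that they came from separate cultures, so the p-values measure only the spread between these samples.

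The first 10 min brought up the genes of the cbb3-type cytochrome c oxidase, a high-affinity terminal oxidase used at low oxygen. fixN rose by 2.21 ± 0.23 (4.63-fold, adjusted p = 0.000127), fixP by 1.80 ± 0.23 (adjusted p = 0.000782) and fixQ by 1.59 ± 0.15 (adjusted p = 6.25e-05). Of the 8 measured genes of the cbb3 oxidase list, 6 rose (7 adjusted over the list alone), and the list shift held with an estimated correlation between genes (adjusted p = 0.000542). Dshi_1660, a BadM/Rrf2 family regulator, rose by 1.68 ± 0.21, and Dshi_2622, a protein of unknown function, by 1.86 ± 0.24. In all, 14 genes passed limma's test at 10 min, each of them a rise of at least 2-fold, and 68 had an unadjusted p under 0.05. At 5 min limma called 0 genes, and 35 had an unadjusted p under 0.05, where 188.75 would be expected by chance. With the anaerobic sample in Cy5 alone 54 genes passed at 5 min, all as falls, and with it in Cy3 alone 33 passed, all as rises. Both are signals brighter in Cy3, and the 2 orientations of a 5 min sample correlated by −0.025, −0.477 and −0.219 in replicates 1, 2 and 3. The direction of these calls goes with the dye. Whether single ones among them belong to the shift was not tested. The median of the cbb3 oxidase list at 5 min lay between 0.477 and 0.65 in other normalizations and dye orientations. fixN already stood at 1.03 ± 0.23 at 5 min, with an adjusted p of 1. The denitrification list test also pointed up at 5 min (adjusted p = 0.336 with an estimated correlation), with medians of 0.64, −0.001 and −0.002 in replicates 1, 2 and 3. The count at 10 min was 5 without 10 min replicate 2 and 26 without 15 min replicate 2. None of the calls at 10 min held without replicate 1 throughout. With the anaerobic sample in Cy5 alone, 24 genes rose and 50 fell at 10 min.

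**Figure D1:**
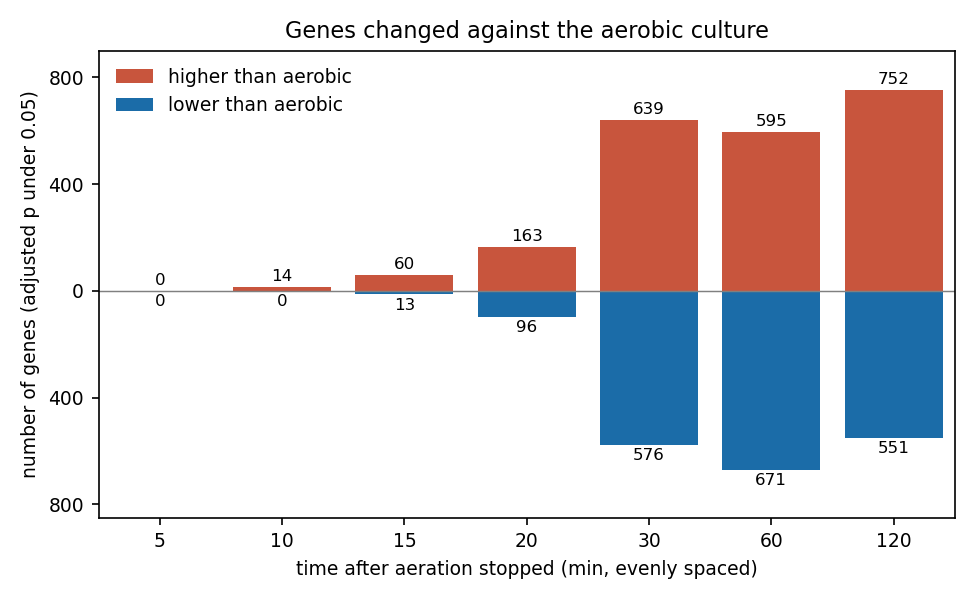
Number of genes with an adjusted p under 0.05 in limma at each time after aeration stopped (x axis, min, evenly spaced), as rises (upward bars) and falls (downward bars); 3775 genes were tested. Calls went from 0 at 5 min to 1303 at 120 min, and falls were first called at 15 min.

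At 15 and 20 min, single genes of tetrapyrrole synthesis, stress proteins and regulators joined the oxidase, and some genes of the aa3-type oxidase fell. bchE, the oxygen-independent cyclase of bacteriochlorophyll synthesis, rose by 2.81 ± 0.36 at 15 min and 3.64 ± 0.36 at 20 min (adjusted p = 1.03e-05). hemN (Dshi_0541), the oxygen-independent coproporphyrinogen III oxidase of heme synthesis, rose by 2.73 ± 0.37 and 3.05 ± 0.37, and hemA (Dshi_1182), 5-aminolevulinate synthase, by 1.40 ± 0.18 and 1.71 ± 0.18. The Crp/Fnr family regulator dnrF rose by 2.30 ± 0.30 and 3.22 ± 0.30. The universal stress gene uspA (Dshi_1338) rose by 3.36 ± 0.52 at 20 min and the TraR/DksA family gene Dshi_1411 by 3.09 ± 0.41. Genes of denitrification, the stepwise reduction of nitrate to dinitrogen, followed: norC, the small subunit of nitric oxide reductase, stood at 0.67 ± 0.58 at 15 min (adjusted p = 1) and rose by 3.40 ± 0.58 at 20 min. Of the 29 genes of the denitrification list, 6 rose at 15 min and 15 at 20 min (6 and 18 adjusted over the list alone; adjusted p = 0.246 and 0.142 with an estimated correlation). The list's medians in replicates 1, 2 and 3 were −0.08, 1.74 and 0.10 at 15 min, where replicate 2 alone stood high, and 1.15, 1.67 and 0.82 at 20 min. In other normalizations and dye orientations the median of the mean ratios at 15 min (0.56) lay between 0.100 and 0.985. At 10 min the list test had pointed up (adjusted p = 0.573 with an estimated correlation) with a list median of −0.03, and replicate medians of −0.09, 0.03 and −0.02. At 20 min ctaC (Dshi_1140), subunit II of the aa3-type oxidase, fell (log2 ratio −1.25 ± 0.20), as did its assembly gene ctaG (−1.07 ± 0.12), the methionine synthase gene bmt (−1.09 ± 0.16) and fnrL, the Crp/Fnr family gene beside the cbb3 cluster (−1.05 ± 0.19).

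Limma called 60 rises and 13 falls at 15 min, and 163 rises and 96 falls at 20 min. These counts leaned on single samples: without replicate 2 of that time 29 genes passed at 15 min, each a rise, and 169, 155 and 154 genes passed at 20 min without replicates 1, 2 and 3. Both counts were lowest without replicate 1 throughout. With the spread of 15 and of 20 min alone 0 and 83 genes passed. Replicate 2 at 15 min resembled replicate 2 at 20 min (correlation across genes 0.98). Without both of these samples, an alternative chosen after seeing the data, 33 genes passed at 15 min and 179 at 20 min. One array of 20 min replicate 3 had 12.4% of its probes well above background.

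At 30 min the denitrification genes led the rises. norC rose by 5.35 ± 0.58 (40.8-fold, adjusted p = 3.65e-06), cycA (Dshi_3169), a class I cytochrome c gene, by 5.18 ± 0.43 (36.4-fold), norB, the large subunit of nitric oxide reductase, by 4.79 ± 0.49, nirS, the cytochrome cd1 nitrite reductase that the array annotation calls hydroxylamine reductase, by 4.79 ± 0.54, and nosZ, nitrous oxide reductase, by 4.27 ± 0.41. Of the 29 list members 27 rose at 30 min, 27 at 60 min and 25 at 120 min, and the same numbers passed adjusted over the list alone. The list's median log2 ratio was 3.58, 3.04 and 2.90 (adjusted p = 0.0774, 0.126 and 0.142 with an estimated correlation). bchE reached 4.32 ± 0.36 (20.0-fold) and its neighbour bchJ 3.97 ± 0.31, hemN (Dshi_0541) 4.05 ± 0.37, the small heat shock gene Dshi_2796 4.19 ± 0.55, the universal stress gene Dshi_2213 4.01 ± 0.36, and ccpA, cytochrome c peroxidase, 3.26 ± 0.33. dmsA (Dshi_2278), a molybdopterin oxidoreductase, rose at least 5.74-fold and its neighbour moeA, of molybdenum cofactor synthesis, at least 2.23-fold.

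The falls at 30 min included genes of the aa3 oxidase, of protein synthesis, of ATP synthase and of uptake systems. ctaC (Dshi_1140) fell (log2 ratio −1.96 ± 0.20, 3.89-fold lower, adjusted p = 1.59e-06), as did rpsP, ribosomal protein S16 (−2.01 ± 0.20), rpsJ, ribosomal protein S10 (−1.98 ± 0.26), the elongation factor gene tsf (−1.73 ± 0.33), the chaperonin gene groEL (−1.56 ± 0.17) and atpD, the beta subunit of ATP synthase (−1.39 ± 0.14). Solute-binding protein genes fell as well, ugpB (Dshi_0547) to −2.05 ± 0.24 and the sugar-binding rbsB (Dshi_0390) to −1.51 ± 0.22. The gene for sulfite oxidase, Dshi_2981, fell to −1.41 ± 0.12. In all, 639 genes rose and 576 fell at 30 min, of which 172 and 121 changed at least 2-fold. With the spread of 30 min alone 282 genes passed, and among samples left out the count was lowest without replicate 1 throughout. With the scanner's own processed signals the split was 439 rises and 645 falls.

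**Figure D2:**
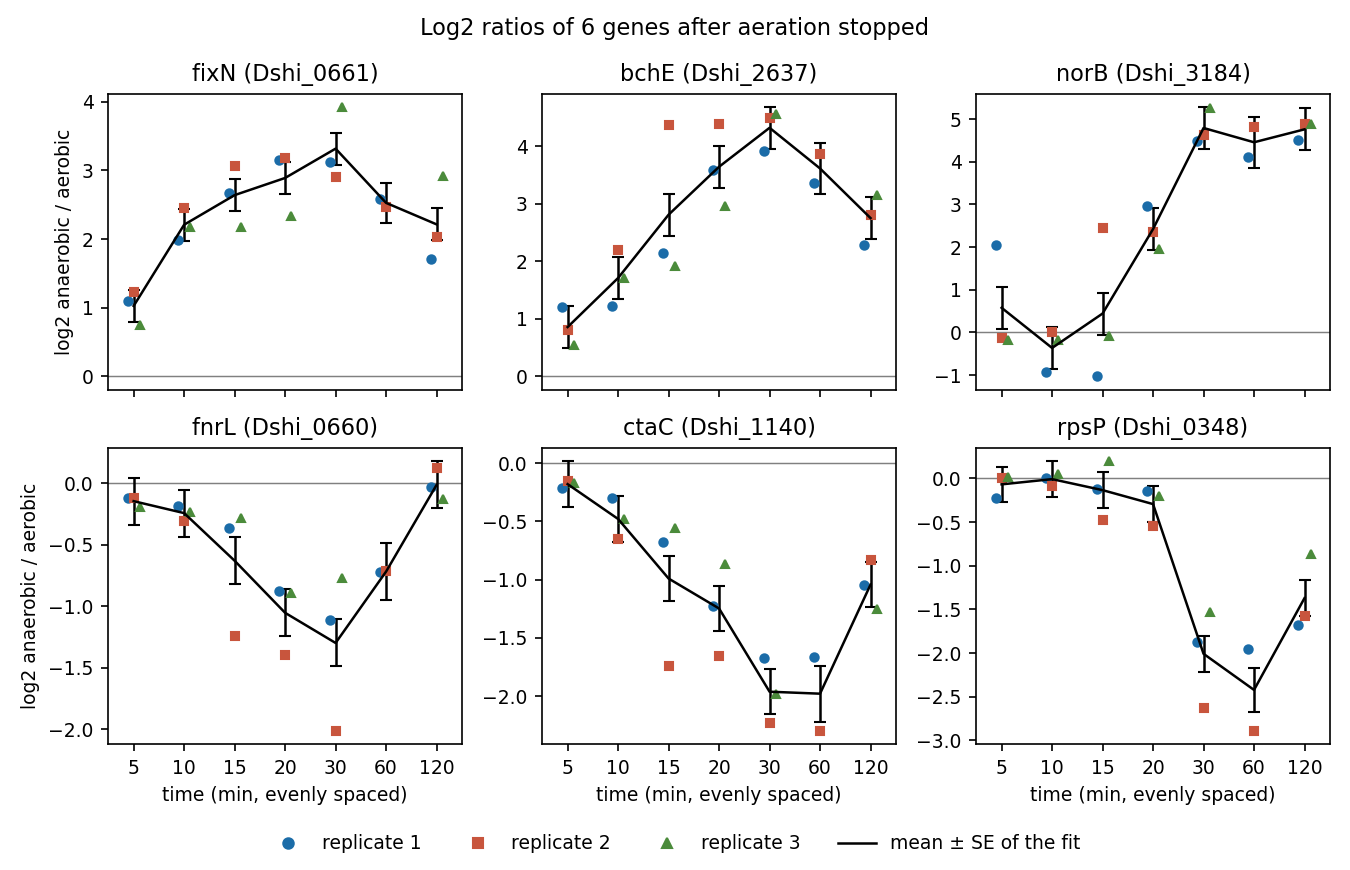
Log2 ratio of anaerobic over aerobic RNA for 6 genes (panels) at each time after aeration stopped (x axis, min, evenly spaced). Points are biological replicates marked by number, lines join the means and bars are the SE of the fit. The mean of norB was 0.44 at 15 min and 4.79 at 30 min, fixN rose from 10 min, fnrL was lowest at 30 min (−1.30) and back at −0.01 at 120 min, and rpsP was lowest at 60 min (−2.42).

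At 60 min the denitrification and cbb3 genes stayed up, and genes of protein synthesis led the falls. norB stood at 4.46 ± 0.60 (21.9-fold), Dshi_3186, a von Willebrand factor type A gene beside norCBQ, at 4.90 ± 0.41, and fixN at 2.53 ± 0.29. rplL, ribosomal protein L7/L12, fell (log2 ratio −3.12 ± 0.42, 8.71-fold lower, adjusted p = 6.1e-05), as did rplW (−2.79 ± 0.29), tufA (Dshi_0223), elongation factor Tu (−2.45 ± 0.35), rpoC, a subunit of RNA polymerase (−1.65 ± 0.20), groEL (−2.08 ± 0.21) and atpX of ATP synthase (−1.58 ± 0.21). Of the 54 ribosomal protein genes 30 fell at 30 min, 46 at 60 min and 24 at 120 min (34, 51 and 25 adjusted over the list alone; adjusted p = 0.63, 0.524 and 0.745 with an estimated correlation). The size differed between replicates: the list's median at 30 min was −0.93, −2.58 and −0.04 in replicates 1, 2 and 3, at 60 min −1.36 and −2.71 in replicates 1 and 2, and at 120 min −1.17, −0.85 and −0.46. Among 24 genes of RNA polymerase and translation factors 13 fell at 60 min (15 adjusted over the list alone), and among 25 aminoacyl-tRNA synthetase genes 9 did (12 adjusted over the list alone), with adjusted p = 0.573 and 0.745 with an estimated correlation; their medians were −0.58 and −0.38 in replicate 1, and −1.80 and −1.33 in replicate 2. In all, 595 genes rose and 671 fell at 60 min, and 379 genes passed with the spread of 60 min alone. Without replicate 2 of that time 288 genes passed, the remaining sample being assumed to vary like the other times, and with the scanner's processed signals 395 rose and 805 fell.

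At 120 min the nitrite and nitric oxide reductase genes were still up, and so were single genes of a hemerythrin-domain protein, of cobalt transport and of a TonB-dependent receptor. nirS stood at 4.97 ± 0.54 (31.2-fold), norB at 4.76 ± 0.49, nosZ at 2.95 ± 0.41 and ccpA at 3.31 ± 0.33. Dshi_2304, a gene with a hemerythrin domain that binds oxygen or nitric oxide at a di-iron site, rose by 3.97 ± 0.24 (15.6-fold, adjusted p = 1.08e-08), its neighbour Dshi_2302 at least 3.01-fold, the BadM/Rrf2 family regulator Dshi_2306 by 2.62 ± 0.21, the cobalt transporter gene cbtA by 2.55 ± 0.13 and the TonB-dependent receptor gene Dshi_1449 by 1.74 ± 0.22. ugpB (Dshi_0547) fell (log2 ratio −2.13 ± 0.24), as did the TRAP transporter gene Dshi_1090 (−1.68 ± 0.20), the solute-binding protein gene Dshi_1652 (−1.66 ± 0.19), sulfite oxidase (−1.58 ± 0.12) and rpsP (−1.37 ± 0.20). Limma called 752 rises and 551 falls, and 820 genes in all without replicate 3 of that time. With the spread of 120 min alone 84 genes passed. The split was 553 and 591 with the scanner's processed signals, and 638 and 658 with median centring. atpD was at −0.13 ± 0.14 and fnrL, whose probes disagreed in sign there, at −0.01 ± 0.19; neither passed the threshold.

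The respiratory chain changed in opposite directions by component. All 8 cbb3 genes were up at 20, 30, 60 and 120 min, with list medians of 2.37, 2.78, 2.44 and 2.20 (adjusted p = 0.0774, 0.246, 0.336 and 0.342 with an estimated correlation). At 15 min 7 of them rose, and that shift held with an estimated correlation (adjusted p = 0.0155). Of the 21 measured genes of the list of other terminal oxidases 7 fell and 3 rose at 30 min, the same adjusted over the list alone, while the list test did not pass (adjusted p = 0.23). That list also holds carbon monoxide dehydrogenase-type cox genes and Dshi_3187 of the nor cluster, a subunit III homologue, which rose by 2.50 ± 0.18 at 30 min. In a list of 7 measured aa3 oxidase genes, drawn up after the data were examined and adjusted with complex I over 14 pairs of list and time only, 3 and 4 fell at 15 and 20 min (4 and 5 adjusted over the list alone; adjusted p = 0.114 and 0.157 with an estimated correlation), with medians at 15 min of −0.43, −1.02 and −0.32 in replicates 1, 2 and 3. Of the same genes 5, 5 and 4 fell at 30, 60 and 120 min (5, 6 and 4 adjusted over the list alone; adjusted p = 0.157, 0.125 and 0.33 with an estimated correlation). Of 14 complex I genes, also listed after the data were examined, 12 rose at 30 min and 12 at 120 min (12 and 13 adjusted over the list alone; adjusted p = 0.114 and 0.097 with an estimated correlation). The 3 measured genes of cytochrome bc1, petA, petB and petC, all rose at 120 min, by 1.00 ± 0.26, 1.10 ± 0.27 and 0.90 ± 0.23, and the same 3 passed adjusted over the list alone. Without replicate 3 of 120 min none of the 3 passed, at log2 ratios of 0.71, 0.69 and 0.55, and the list test did not pass (adjusted p = 0.0609). Of 17 ATP synthase genes 8 fell at 30 min and 0 at 120 min, while 3 and 4 rose (8 fell at 30 min adjusted over the list alone; adjusted p = 0.524 with an estimated correlation). The ATP synthase median at 30 min was −0.09, −1.59 and −0.19 in replicates 1, 2 and 3.

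Regulators of the Crp/Fnr family, to which the oxygen and nitric oxide sensors of many proteobacteria belong, went both ways. Of 10 measured members 6 rose and 2 fell at 30 min, the same adjusted over the list alone (adjusted p = 0.351 with an estimated correlation). dnrF rose by 3.60 ± 0.30, dnr (Dshi_3191) by 3.56 ± 0.31, dnrD by 2.36 ± 0.16 and Dshi_2108 by 0.67 ± 0.14, and fnrL fell (log2 ratio −1.30 ± 0.19). Dshi_2528 rose by 0.41 ± 0.10 and Dshi_3110 fell (log2 ratio −0.25 ± 0.08), a call lost without any one of the 30 min replicates. Dshi_2521 was at 0.01 ± 0.13, with probes that disagreed in sign. At 30 min Dshi_3764 was not well above background in the anaerobic channel, nor Dshi_3844 in either channel, which is 1 of the 6 counted rises.

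Tetrapyrrole and cytochrome c genes rose in part of their lists. Of 14 heme biosynthesis genes 7 rose and 2 fell at 30 min, the same adjusted over the list alone (adjusted p = 0.524 with an estimated correlation), with medians of 0.34, −0.004 and 0.94 in replicates 1, 2 and 3. At 20 min the list test pointed up with a median of −0.02 (adjusted p = 0.637 with an estimated correlation) and replicate medians of 0.13, −0.08 and 0.03. Both hemN genes and both hemA genes were among the rises, with hemA (Dshi_3190), which lies in the nor region, at 3.34 ± 0.33. Of 40 photosynthesis genes 18 rose at 30 min and 16 at 60 min, and at 120 min 4 rose and 8 fell (18 and 17 rises adjusted over the list alone; adjusted p = 0.631 and 0.573 with an estimated correlation). The photosynthesis medians at 120 min were 0.11, −0.35 and 0.40 in replicates 1, 2 and 3. Apart from bchE and bchJ the rises at 30 min were small, with bchG at 1.15 ± 0.17, and the antenna gene pucB fell at 120 min (log2 ratio −0.84 ± 0.10). Of 17 genes of cytochrome c maturation 7 rose and 1 fell at 30 min (7 and 2 adjusted over the list alone; adjusted p = 0.524 with an estimated correlation), with medians of 0.17, 0.03 and 0.38 in replicates 1, 2 and 3, among them ccmC (0.94 ± 0.12) and cycH (1.29 ± 0.13), of heme attachment, and cycA (Dshi_3169), which is a cytochrome itself.

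Genes of the tricarboxylic acid cycle went both ways. sucA, of 2-oxoglutarate dehydrogenase, rose by 1.64 ± 0.17 at 30 min and 1.34 ± 0.17 at 120 min, sucD, of succinyl-CoA synthetase, by 1.49 ± 0.20 and 1.59 ± 0.20, and sdhA, of succinate dehydrogenase, by 1.08 ± 0.16 and 1.11 ± 0.16. Of the 23 measured cycle genes 10 rose and 5 fell at 30 min, and 11 rose and 4 fell at 120 min (11 and 5 adjusted over the list alone; adjusted p = 0.573 with an estimated correlation). The adjusted p of the list at 30 min was 0.161. Of 18 genes of the Entner-Doudoroff pathway and glycolysis 3 fell at 30 min and 5 at 120 min, where 1 rose, the same adjusted over the list alone, while the list test did not pass (adjusted p = 0.131 at 120 min); eno, enolase, fell to −0.97 ± 0.20 at 30 min. Of 5 ethylmalonyl-CoA pathway genes 1 rose and 1 fell at 30 min, the same adjusted over the list alone, while the list test did not pass (adjusted p = 0.861).

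Genes of the stress lists went both ways. Of 21 genes of the universal stress and stringent response list 6 rose at 30 min, the same adjusted over the list alone, while the list test did not pass there (adjusted p = 0.0557); they include the UspA genes Dshi_1338, Dshi_2213 and Dshi_2686 and the TraR/DksA genes Dshi_0812 and Dshi_1411. Dshi_0812 rose by 3.31 ± 0.29 and Dshi_2686 by 3.11 ± 0.36. Of 22 genes for chaperones and proteases 5 rose and 5 fell at 60 min (5 and 6 adjusted over the list alone; list adjusted p = 0.968), with groEL and groES among the falls (−1.90 ± 0.19 for groES). Of 26 genes of oxidative stress defence 6 rose and 6 fell at 30 min (7 and 9 adjusted over the list alone; list adjusted p = 0.627), with ccpA among the rises and trxA, thioredoxin, among the falls (−0.90 ± 0.14). Of 28 molybdenum cofactor genes, a list that also holds molybdoenzymes, 10 fell and 3 rose at 120 min (12 and 3 adjusted over the list alone; adjusted p = 0.63 with an estimated correlation), with medians of −0.11, −0.02 and −0.52 in replicates 1, 2 and 3, among the falls moaA, at −0.76 ± 0.14, or −0.46 without replicate 3 of that time. Of 7 genes of dimethyl sulfoxide and trimethylamine oxide reduction 2 rose at 30 min, dmsA (Dshi_2278) among them, the same adjusted over the list alone, while the list test did not pass (adjusted p = 0.324).

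**Figure D3:**
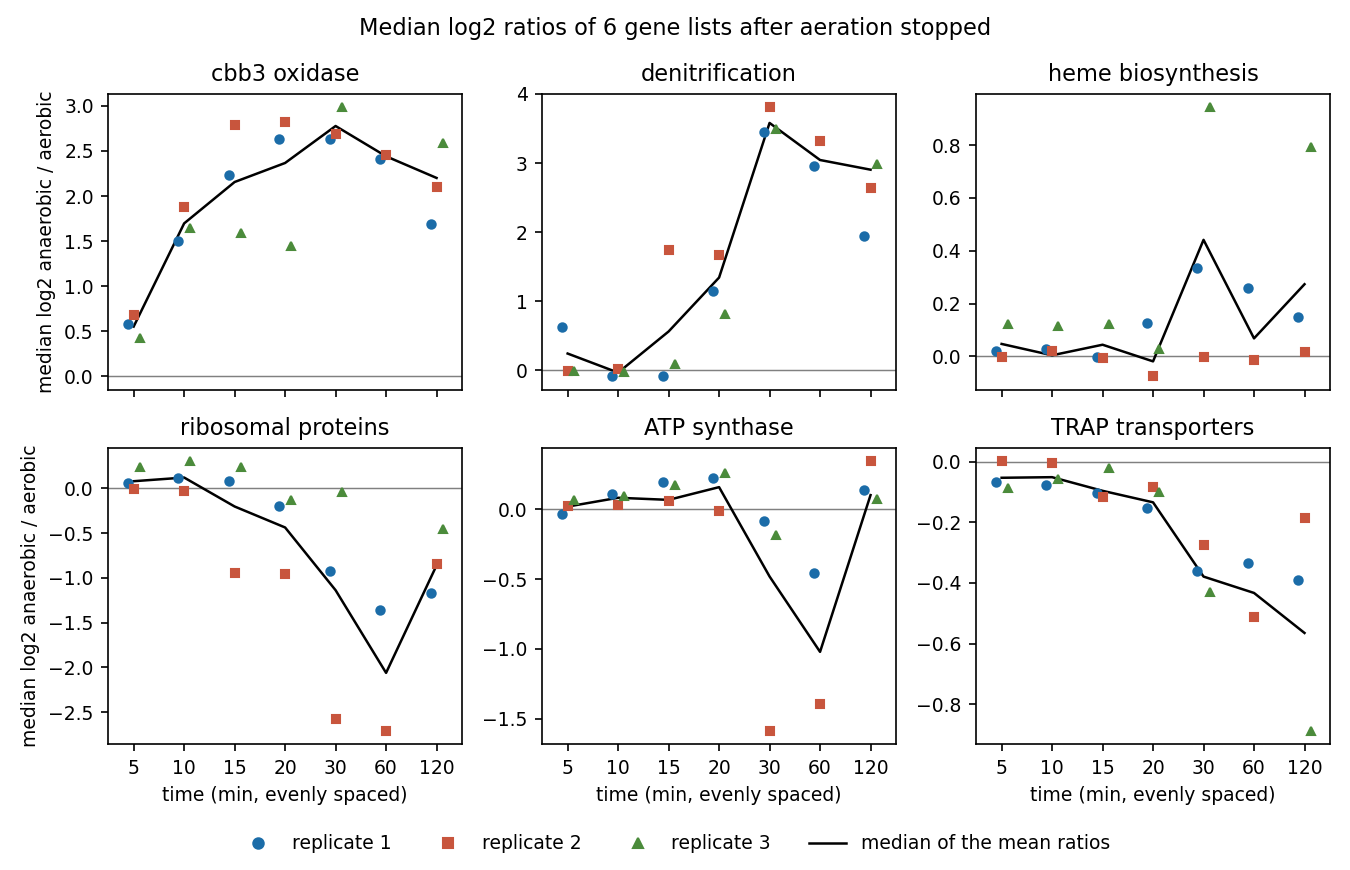
Median log2 ratio of 6 gene lists (panels) in each biological replicate, against time after aeration stopped (x axis, min, evenly spaced); points are replicates marked by number and the line joins the list medians of the mean ratios. The denitrification median rose to 3.58 at 30 min, and the ribosomal protein medians of replicates 1, 2 and 3 at 30 min were −0.93, −2.58 and −0.04.

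Between 5 and 30 min the denitrification genes led the rises. cycA (Dshi_3169) was higher at 30 min by 4.68 ± 0.61 (adjusted p = 0.00012), norC by 4.64 ± 0.82, norB by 4.21 ± 0.69 and nosZ by 4.19 ± 0.58, and 26 of the 29 list members rose between these times (27 adjusted over the list alone; adjusted p = 0.115 with an estimated correlation). rpsP was lower at 30 min by a log2 difference of −1.94 ± 0.29, rpsJ by −1.92 ± 0.37, ctaC (Dshi_1140) by −1.78 ± 0.28 and ugpB (Dshi_0547) by −1.84 ± 0.34. In all, 301 genes were higher and 227 lower at 30 than at 5 min; with the scanner's processed signals the split was 210 and 236, and with a fixed replicate block 432 each. No slide held arrays of both times, and with the slide as a random block 682 genes passed. The count was 329 without 5 min replicate 2 and 315 without 5 min replicate 3. It was 244 with the anaerobic sample in Cy3 alone, and lowest without replicate 1 throughout.

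Between 30 and 120 min single genes changed in both directions, and the medians of some lists moved back towards 0. cbtA rose by 1.73 ± 0.18 (adjusted p = 0.000296), cobW, a cobalamin synthesis gene beside it, by 1.72 ± 0.25, and atpD by 1.26 ± 0.20. nosY, of nitrous oxide reductase maturation, fell (log2 difference −1.95 ± 0.34, adjusted p = 0.00835), as did the alkylhydroperoxidase gene Dshi_2969 (−1.66 ± 0.30) and pucB (−0.89 ± 0.14). Of the denitrification list 4 genes fell (9 adjusted over the list alone), and its median was lower at 120 min in replicates 1, 2 and 3 (log2 differences −1.51, −1.18 and −0.51). The cbb3 median was lower as well (−0.95, −0.59 and −0.40), with 0 of its genes called (2 adjusted over the list alone), and the aa3 median was higher by 0.51, 1.29 and 0.51, again with 0 called (4 adjusted over the list alone). The adjusted p was 0.529 for each of these 3 lists with an estimated correlation. In all, limma called 23 rises and 19 falls. With the replicate number as a block, which paired these samples, 116 genes passed (70 rises and 46 falls; 153 with a random block), the 42 among them, and 191 passed with the slide as a random block. The count was 84 without 15 min replicate 2, 26 without 30 min replicate 1 and 130 without 120 min replicate 3. It was 19 without replicate 3 throughout, 6 with the anaerobic sample in Cy3 alone and 0 with the spread of the 2 times alone. None of the calls held without replicate 1 throughout. With the scanner's processed signals 17 rises and 7 falls passed, and 37 and 16 with the deposited series matrix values.

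Between 5 and 120 min 367 genes were higher and 158 lower (193 and 126 with the scanner's processed signals), led by Dshi_3186 (log2 difference 4.69 ± 0.48, adjusted p = 1.27e-05), nirS (4.31 ± 0.76) and Dshi_2304 (3.91 ± 0.34), with ugpB (Dshi_0547, −1.92 ± 0.34) and Dshi_1090 (−1.66 ± 0.28) among the falls. Of the TRAP transporter genes 22 were lower and 5 higher (28 and 5 adjusted over the list alone; adjusted p = 0.529 with an estimated correlation). The count was 307, 257 and 253 without 5 min replicates 1, 2 and 3, and 588 with the slide as a random block. It was 227 with the anaerobic sample in Cy3 alone, and lowest without replicate 1 throughout. No slide held both times. Over the 7 times 658 genes (17.4%) passed the F test of the differences from 5 min. That count was 417 without replicate 3 and lowest without replicate 1. Between consecutive times limma called 57 rises and 44 falls from 20 to 30 min (81 and 100 with the replicate number as a block, 39 and 56 with the scanner's processed signals) and 1 rise from 30 to 60 min. The count from 20 to 30 min was 63 and 52 without 20 min replicates 1 and 3, and 160 and 221 without 120 min replicates 2 and 3. It was lowest without replicate 1 throughout. No slide held arrays of both 20 and 30 min, so this step cannot be told apart from the change of slide. With the slide as a random block 129 genes passed. Limma called 0 genes from 5 to 10, 10 to 15, 15 to 20 and 60 to 120 min, where 16, 32, 73 and 395 genes had an unadjusted p under 0.05. From 60 to 120 min 8 genes passed with a fixed replicate block and 15 with a random one. With the slide as a random block, 6 genes passed from 30 to 60 min and 18 from 60 to 120 min.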

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

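Tests chosen after the results were seen were those of assignments within replicate numbers, of an exchange of arrays, of a replicate ahead of the others and of a slide effect, together with the correlation of dye-pair differences; the predictions of the other tests were written before their values were computed. The response differed between times by tests of the difference itself. Over the 7 times 658 genes passed the F test (417 without replicate 3, and fewest without replicate 1). Of 100 assignments of the 20 samples to the times, the real one included, 2 gave as many. These ignore the structure of replicates, and the highest other gave 1028. Of 100 assignments within replicate numbers only the real one (1) gave as many, and the highest other gave 7, or 6 where the replicate number was a block (again 1 of 100), which argues against an arrangement by chance. Within each replicate number, no slide held times both before 30 min and from 30 min on. These assignments break up the slides as well, so they cannot exclude an effect of the slides. Between 5 and 30 min 528 genes differed, as 1 of the 10 splits of the 6 samples, and the highest other split gave 0. Between 5 and 120 min 525 genes differed, and between 20 and 30 min 101, each again 1 of 10 splits with 0 as the highest other. Between 30 and 120 min 42 genes differed, and 3 of the 10 splits gave as many, with 375 as the highest other. In each of these 4 comparisons 10 splits are too few for a share under 0.05. The splits with 375 and 244 genes set both samples of replicate 2 against both samples of replicate 3, which points to a structure of replicates and slides. The numbers paired these samples, and among the 4 splits that part all 3 pairs the others gave 3, 0 and 0 genes.

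The sample of replicate 2 at 15 min was nearly that of replicate 2 at 20 min: their correlation across genes was 0.984, against 0.416 to 0.947 in 15 other pairs of adjacent times, and the SD of their difference was 0.285 times that expected from array noise. That ratio was within the bound set beforehand for hybridisations of a single RNA. The noise was itself estimated from the dye-pair differences of these samples, which an exchange of arrays would widen, so the low ratio decides nothing. A single RNA would not give dye-pair differences that oppose each other, and these correlated by −0.669, against −0.236 to 0.882 in the other pairs. This correlation, chosen after the results were seen, argues against a single RNA. An exchange of the 15 and 20 min arrays of one dye is a candidate explanation: the dye orientations correlated better crosswise than as labelled by 0.11, against −0.178 to 0.068 elsewhere. Such an exchange would also lower the SD of the difference and set the dye-pair differences against each other. Whether the culture of replicate 2 ran ahead stays open. An index of the response (share of the mean 30 min change) was highest in replicate 2 in 3 of 4 values, those of the 2 dye orientations at 10 and 20 min. The exception was 20 min with the anaerobic sample in Cy5 (0.438, against 0.562 in replicate 3). At 5 min the index was highest in replicate 1 (0.168 against 0.05). These values cannot decide this, since they include 20 min arrays that an exchange would concern. With the anaerobic sample in Cy5 and in Cy3, the index of replicate 2 was 0.788 and 0.4 at 15 min, and 0.438 and 0.706 at 20 min. Each of these lay above the values of replicates 1 and 3 at 15 min (0.14 to 0.189). An exchange between the 15 and 20 min arrays would therefore not account for the high 15 min index of replicate 2. An effect of the slide that held 5 and 15 min replicate 2 cannot be told apart from these, since their deviations correlated by 0.301, between the bounds set for it, and that slide held replicate 2 alone.

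Ribosomal protein genes were lowest at 60 min, by a gap of −1.06 on the log2 scale to the mean of 30 and 120 min. Centring in place of loess kept 0.899 of the gap, and the dye orientation with the smaller gap kept 0.929, which argues against normalization and dye. Both shares are of the gap with replicate 3 included at 30 and 120 min. With replicates 1 and 2 alone, those present at 60 min, 0.611 of the gap was left. The absence of replicate 3 at 60 min cannot account for that share. The remainder came from including replicate 3 at 30 and 120 min, where its medians were −0.04 and −0.46, without a value at 60 min. The dip itself was not established, since 0 of the 54 genes differed between 30 and 60 or 60 and 120 min (0 and 6 adjusted over the list alone; adjusted p = 0.576 and 0.529 with an estimated correlation), and the steps were −0.43 and 0.19 in replicate 1 and −0.13 and 1.86 in replicate 2. A passing slowdown of protein synthesis is an untested biological explanation.

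The regulator gene fnrL fell at 20 and 30 min (−1.30 at 30 min) while the fix genes beside it rose. A single deviating probe is argued against by the highest of its 3 probes, at −0.835. Normalization and dye are argued against by the highest value among 6 other settings, −1.168. Negative control of fnrL by its own product is a biological hypothesis, consistent with these values and not tested by the design, which holds no mutant.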

How the results depend on the processing

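Alternatives chosen after the data were seen were the use of the brighter array alone for 20 min replicate 3, the omission of 15 and 20 min replicate 2 together, the aa3 oxidase and complex I lists, and every alternative for 20 against 30 min; the others were planned. Counts at single times, in the 4 differences and the F test below and of list shifts that are not named here stayed within 1.5 times the value reported. With the spread taken from the compared times alone, 48, 0, 83, 282, 379 and 84 genes passed at 10, 15, 20, 30, 60 and 120 min. Between 30 and 120 min 0 passed, between 5 and 120 min 271 and between 20 and 30 min 55. Fewer samples then estimate each spread, but the count at 10 min rose from 14. Under the shared spread 35 and 68 genes had an unadjusted p under 0.05 at 5 and 10 min, where 188.75 would be expected by chance. This points to a shared spread that was too wide at the early times and may be too narrow at the late ones. A fixed replicate block gave 32 genes at 10 min, 466 at 20 min, 864 between 5 and 30 min, 116 between 30 and 120 min, 181 between 20 and 30 min and 1042 in the F test. A random replicate block gave 881, 153, 808 and 200 genes in 30 against 5, 120 against 30, 120 against 5 and 30 against 20 min, and 1103 in the F test. Samples with one replicate number deviated together in 51 of 57 pairs (correlation over 0.1, range −0.112 to 0.823), and 19 of 20 samples correlated best with their own number. Between 5 and 30 min the correlations were 0.067, 0.54 and 0.279 in replicates 1, 2 and 3, and between 5 and 120 min 0.079, 0.471 and 0.206. These 2 comparisons were not taken as paired because replicate 1 lay under 0.1, although replicates 2 and 3 deviated together. The replicate block, which paired samples in 120 against 30 min and 30 against 20 min, kept all 42 and 101 calls there and added others. The slide as a random block gave 191 genes between 30 and 120 min.

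With the anaerobic sample in Cy5 alone 54, 74 and 117 genes passed at 5, 10 and 15 min (65 rises and 52 falls at 15 min). In Cy3 alone 33 and 41 passed at 5 and 10 min, 244, 6, 227 and 34 in 30 against 5, 120 against 30, 120 against 5 and 30 against 20 min, and 310 in the F test; at 15 min 78 rose and 4 fell. The scanner's processed signals gave 23 genes at 10 min, 24 between 30 and 120 min and 319 between 5 and 120 min, and moved the median of all genes to −0.119 at 30 min and −0.147 at 60 min. At 120 min they gave 553 rises and 591 falls. Without background subtraction 71 genes differed between 30 and 120 min (46 rises and 25 falls). The stricter filter on dim probes, with fewer genes tested, gave 67 between 20 and 30 min. Aquantile leaves log ratios as they are, so its equal counts are no test. The brighter array alone for 20 min replicate 3 gave 23 genes at 10 min. Without 15 and 20 min replicate 2, 27 genes passed at 10 min, 33 at 15 min and 79 between 30 and 120 min (31 rises and 48 falls). Of 87 list shifts 2 passed with an estimated correlation, both of the cbb3 oxidase, and 68 with fry. Fewer samples, an unequal spread and fewer genes are named above as possible causes. The opposite calls of the 2 dye orientations at 5 min go with the dye. No other cause was tested in any of these.

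Leaving out one sample or one replicate number gave 0 to 2 genes at 5 min, 0 to 26 at 10 min, 5 to 77 at 15 min, 19 to 371 at 20 min, 467 to 1428 at 30 min, 288 to 1583 at 60 min and 437 to 1489 at 120 min. It gave 98 to 723 between 5 and 30 min, 0 to 130 between 30 and 120 min, 64 to 692 between 5 and 120 min, 31 to 221 between 20 and 30 min, 59 to 798 in the F test and 71 to 90 list shifts. The lowest counts came without replicate 1 throughout, except at 5 min, at 60 min (without replicate 2 of that time) and for the lists (without replicate 3). Of 5126 values of single named genes under the 38 other alternatives 118 no longer passed the threshold, 4 newly passed and 0 called values turned sign. Many of these alternatives left out a sample of a time that the value did not use, so the losses were uneven. Of 135 values 44 no longer passed with the spread of the compared times alone, and 12 without replicate 3. Among replicate numbers left out, most were lost without replicate 1. Among list medians at least 0.1 in size, those that turned sign at 30, 60 or 120 min in other normalizations and dye orientations were of gene transfer agent and iron genes at 30 min (1 of 6 each), universal stress genes at 60 min (1 of 6) and DMSO and TMAO reduction at 60 min (2 of 6); medians nearer 0 were not counted, and some crossed it, such as that of the cycle genes at 60 min (−0.271 to 0.105). Among calls at 30, 60 and 120 min, 54, 80 and 37 genes were dim in the anaerobic channel, and 30, 20 and 43 had probes that disagreed in sign.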

Other observations

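The correlations between dye orientations were computed after the results were seen, and the list tests were planned. Flagellar and chemotaxis genes were up late: of 37 measured genes 18 rose at 30 min, 17 at 60 min and 29 at 120 min, while 1 and 2 fell at 30 and 60 min (19, 23 and 30 rises adjusted over the list alone; adjusted p = 0.524, 0.487 and 0.364 with an estimated correlation). flgH, of the basal body, rose by 0.79 ± 0.11 at 120 min and flgG, of the rod, by 0.85 ± 0.14. In the lists of uptake systems more genes fell than rose. Of 63 TRAP transporter genes, for uptake of organic acids, 30, 26 and 34 fell at 30, 60 and 120 min and 7, 5 and 7 rose (32, 28 and 34 falls adjusted over the list alone; adjusted p = 0.641, 0.739 and 0.516 with an estimated correlation), with medians at 120 min of −0.39, −0.19 and −0.89 in replicates 1, 2 and 3. Among the rises was Dshi_3154, at 2.20 ± 0.25 at 30 min. Of 16 genes of amino acid and peptide ABC transport 9 fell at 30 min and 11 at 120 min (9 and 12 adjusted over the list alone; adjusted p = 0.573 and 0.524 with an estimated correlation), with livH, a branched-chain amino acid permease gene, at −0.74 ± 0.11 and −0.80 ± 0.11; the list's medians at 120 min were −0.47, −0.04 and −1.30 in replicates 1, 2 and 3. Of 15 phosphate uptake genes 11 fell and 3 rose at 30 min, the same adjusted over the list alone (adjusted p = 0.462 with an estimated correlation). The phosphate-binding protein gene Dshi_1533 fell (log2 ratio −1.43 ± 0.15), and the rises hold the phosphate transporter gene Dshi_0542 (2.89 ± 0.42) and sdhD, a succinate dehydrogenase gene that the list's pattern took in (1.38 ± 0.20). Of 27 genes of type IV secretion and conjugation 17 fell at 30 min and 2 at 120 min (17 and 0 adjusted over the list alone; adjusted p = 0.524 and 0.796 with an estimated correlation), with virB4 (Dshi_3641) at −0.69 ± 0.12. The medians of that list at 120 min were −0.16, 0.21 and −0.61 in replicates 1, 2 and 3.

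Storage, nitrogen and iron genes rose in part. Of 14 genes of the polyhydroxyalkanoate list 6 rose at 20 min, 9 at 30 min and 10 at 120 min (7, 11 and 13 adjusted over the list alone; adjusted p = 0.0774, 0.142 and 0.142 with an estimated correlation). phbC, the polymer synthase, rose by 1.62 ± 0.15 at 30 min, and the list also holds subunits of a cation/proton antiporter, such as phaA (0.99 ± 0.13), which do not make the polymer. Of 21 nitrogen assimilation genes 7 rose at 30 min and 8 at 120 min, while 3 and 2 fell (9 and 8 rises adjusted over the list alone; adjusted p = 0.228 with an estimated correlation at 120 min, and 0.103 at 30 min with the preset one), with the urease gene ureB at 1.18 ± 0.13. Of 21 genes of iron-sulfur cluster assembly and iron uptake 11 rose at 120 min, the same adjusted over the list alone (adjusted p = 0.524 with an estimated correlation), with medians of 0.21, 0.20 and 0.91 in replicates 1, 2 and 3. Of 8 sulfur oxidation genes 5 fell at 30 min, the same adjusted over the list alone (adjusted p = 0.573 with an estimated correlation), with medians of −0.50, −0.17 and −0.86 in replicates 1, 2 and 3. Of 67 genes of transposases and integrases 10 rose at 60 min (7 adjusted over the list alone; adjusted p = 0.602 with an estimated correlation). Of 11 gene transfer agent genes, a list that also holds prophage genes, 2 rose at 30 min, the same adjusted over the list alone, and the list test did not pass (adjusted p = 0.404); the sign of its median there turned in 1 of 6 other normalizations and dye orientations. Of 19 genes of quorum sensing and the CtrA phosphorelay 4 rose and 4 fell at 60 min (4 and 5 adjusted over the list alone; list adjusted p = 0.968). No gene matched the list of Rnf and Nqr complexes.

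Genes with no known role were among the strongest rises at several times. Dshi_0715, a hypothetical protein, rose by 3.65 ± 0.37 at 20 min and 4.33 ± 0.37 at 30 min, and Dshi_0814 by 3.40 ± 0.38 and 4.22 ± 0.38. Dshi_1412, beside the TraR/DksA gene Dshi_1411, rose by 4.15 ± 0.38 at 30 min, and the OmpW family gene Dshi_1299 by 3.97 ± 0.32. The 2 dye orientations of a sample correlated across genes between −0.477 and 0.932.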
